A study of Mus musculus with 4 samples.

How the data were processed

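RNA from pooled mouse livers was measured on 4 arrays with 2 colours, each carrying a CLA pool and an LA pool, and the table used here is the authors' processed table of log ratios, 1 column per array and 22393 features. Per the labels, CLA was in Cy5 on arrays 1 and 2 and in Cy3 on arrays 3 and 4. The deposited values are taken as log10 ratios, since the base, the direction and the normalization are not given in the sources used here; the lowest deposited value was -3.17 and the highest 3.28. Each was multiplied by 3.32 to give log2 ratios, and if the deposited log base were 2 every log2 value in the text would be smaller by that factor. The median of the deposited values was 0.0010, -0.0023, -0.0020 and -0.0011 on arrays 1 to 4, close to 0, and whether the authors centred the arrays is not stated. Scanner intensities, background and spot flags were not used here, so no filter on dim probes could be applied and the signal over background behind each ratio is unknown.

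Genes were named from the annotation of the array's probes. A single symbol was given for 18218 features, several for 16, and none for 4159, which were left out of the tests; features with several symbols were left out too. Gene numbers of 18175 named features were matched to RefSeq genes of assembly GRCm38.p6, used for names only, and changed 0 symbols. Replicate spots, taken as accessions with at least 8 features, were averaged (48 accessions, 484 features), which left 17782 probes. For gene lists, probes of a gene were averaged over 1148 genes with more than 1 probe. Different accessions of 1 gene did not go together across genes, with a Pearson r of 0.026 over 770 pairs (permutation p = 0.46) in the planned reading and 0.062 (permutation p = 0.085) in the turned reading, whereas replicate spots gave r = 0.91 and 0.69 over 48 pairs.

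Each probe was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on the 4 log2 ratios, with 1 coefficient for the part that keeps its sign across the orientations and 1 for the part that changes sign with them, which leaves 2 residual degrees of freedom beside 2.64 prior ones. The planned reading takes the sign-changing coefficient as the CLA effect and the other as the dye effect; the turned reading takes them the other way round. P-values were adjusted by Benjamini and Hochberg's method at 0.05. The design, the alternatives, 45 gene lists and the rule for named genes were fixed before the data were examined. Lists of at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over 45 lists, with an estimated correlation and with fry beside it. Named genes are the 12 with the largest change in each direction past the threshold with 1 sign on all 4 arrays, filled up by smallest p; 35 genes fixed in advance; and, for each shifted list, up to 4 passing members or the 2 with the smallest p.

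The fit was tested on simulated data of 17782 probes. A change of 0.5 log2 was called in 13.4% of changed probes for the sign-changing coefficient and in 11.9% for the other, and a change of 1 log2 in 89.6% and 94.0%. Of the calls made, 7 of 142 for the sign-changing coefficient and 15 of 151 for the other were on unchanged probes. Among 16504 simulated genes, camera with the preset correlation called 10 of 10 lists shifted by 0.25 log2 along with 1 unshifted list, and with an estimated correlation it called 0 of 10. For a shift of 0.5 log2 the preset correlation called 10 of 10 along with 2 unshifted lists and the estimated one again 0 of 10. A list not called with an estimated correlation may therefore still be shifted by that much. Noise in these simulated genes was independent between genes. In the data the estimated correlation of the called lists ran from 0.012 for mitochondrial beta-oxidation to 0.98 for pancreas acinar markers. It was 0.18 for cholesterol synthesis, 0.28 for PPAR-alpha targets and 0.31 for acute phase proteins. How often the preset correlation calls unshifted lists in the data is therefore not known from this simulation.

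Alternatives were median centring, scaling to one spread, no dye term, the other reading, averaging arrays in pairs, robust variance moderation, other thresholds, genes in place of probes and leaving out each array. Removal of a smooth trend over the position on the array (loess, span 0.3, on a grid assumed from the feature numbers), all features, unaveraged spots and the turned reading as a result of its own were added after the values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.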

Results

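Liver RNA from mice with polygenic obesity was compared between a diet with conjugated linoleic acid (CLA, a family of linoleic acid isomers) and a control diet with ordinary linoleic acid (LA), at day 14 of a feeding trial. Each RNA was a pool of 5 or 4 samples, and a CLA pool and an LA pool were labelled with the dyes Cy5 and Cy3 and hybridised together on one array. There were 4 arrays. CLA was in Cy5 on arrays 1 and 2 and in Cy3 on arrays 3 and 4. Each array gave 22393 features without missing values, of which 17782 probes with 1 named gene were tested, for 16504 genes. The labels do not say which arrays share pools. Every limma p-value of a probe or gene therefore measures only the spread between these 4 arrays, and their number limits the precision. The camera p-value at the preset correlation sets the genes of a list against the other genes, so it does not measure the spread of a list mean between arrays. The comparison asks which liver genes, among them those of lipid metabolism, differ between CLA and LA feeding.

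The values allow 2 readings, explained in the next paragraph, which share arrays 1 and 2 and differ in the sign of arrays 3 and 4. Genes of cholesterol synthesis had a negative list mean in both, which rests on the shared arrays 1 and 2 and is not independent evidence. Their mean log2 ratio of CLA over LA was -0.38 ± 0.26 (SD, n = 4 arrays) in one reading and -0.21 ± 0.45 in the other, with camera adjusted p of 0.0016 and 0.00024 at a preset correlation between genes. Neither call was kept with an estimated correlation (adjusted p = 0.92 and adjusted p = 0.67). That setting also called 0 of 10 shifted lists in simulated data, so here and below a call lost with it does not argue against a shift. When the values were read as already turned to CLA over LA, target genes of PPAR-alpha, the nuclear receptor that senses fatty acids, stood 0.32 ± 0.22 higher with CLA. Genes of mitochondrial beta-oxidation stood 0.15 ± 0.11 higher and those of peroxisomal beta-oxidation 0.16 ± 0.12 higher, the latter with its call lost without array 1. Each of these 3 lists had adjusted p = 0.67 with an estimated correlation, and no single probe passed the test in that reading. When the values were read as Cy5 over Cy3, 2995 probes passed, and 0 without array 3 or without array 4 (limma, 5103 and 4333 at an unadjusted p under 0.05). Acute phase, complement, ribosomal protein and proteasome lists were then lower with CLA at the preset correlation, each with adjusted p = 0.92 with an estimated correlation.

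The direction of the deposited ratios is not stated by the labels and is not settled here, so that rises and falls in the planned reading described below hold only if the values are Cy5 over Cy3. Arrays of opposite dye orientation correlated negatively over all features, with a mean Pearson r of -0.88 across features, and the rule set in advance then read the values as Cy5 over Cy3, so that arrays 3 and 4 were turned (the planned reading). Dye bias in values already turned would also give a negative correlation, so this rule could not tell the 2 readings apart. The mean Pearson r was -0.44 over named probes, and the mean Spearman rho over all features was -0.41. The other reading, in which all 4 arrays already run as CLA over LA (the turned reading), was an alternative set in advance and was made a result of its own after the values were seen. On arrays 1 and 2 both readings give CLA over LA if the ratio there is Cy5 over Cy3, which is not stated and was not tested. The opposite direction on these arrays would turn the sign of every result in both readings. Over named probes the correlation across features was -0.62 between arrays 1 and 3, -0.20 between arrays 2 and 3, 0.37 between arrays 1 and 2 and 0.73 between arrays 3 and 4. Features are not independent replicates. Olfactory and vomeronasal receptor probes, for genes known mainly from the nose, were called in the planned reading at 14.3% of 895 probes, against 17.0% of the other 16887 probes. A further 473 of the 4159 features without a named gene lay over 10-fold from 0 and changed sign with the dye orientation, all in the same direction, with a median log2 ratio of -8.67 on array 1 and 8.54 on array 4. As a hypothesis, the share of receptor probes called and these unnamed features favour the turned reading. A CLA effect in part of the other probes stays open.

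**Figure D1:**
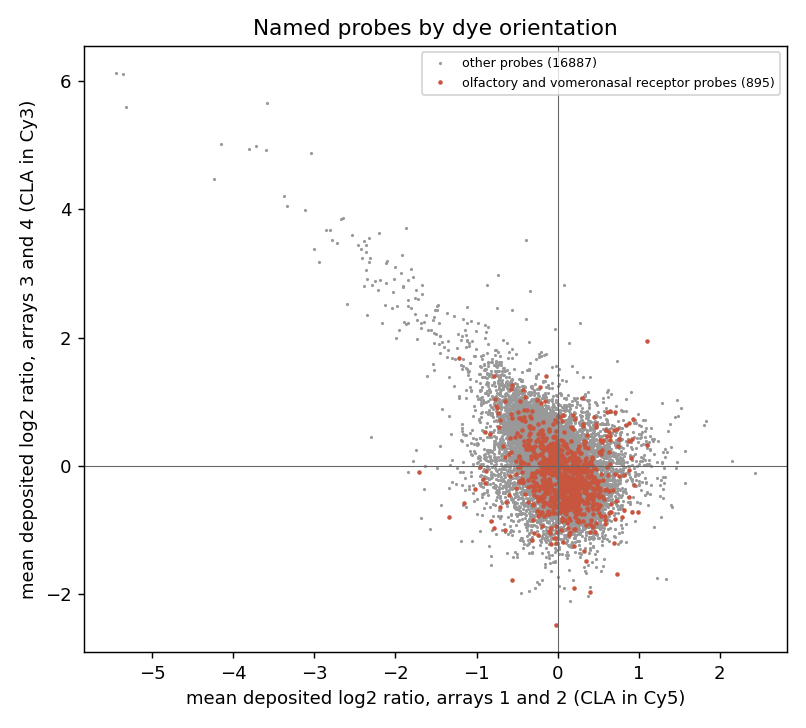
Each point is a named probe, with its mean deposited log2 ratio on arrays 1 and 2 (CLA in Cy5) on the x axis and on arrays 3 and 4 (CLA in Cy3) on the y axis. Grey points are 16887 probes and red points are the 895 olfactory and vomeronasal receptor probes, which lie mostly within the central cloud, while the probes farthest from 0 lie at the upper left, negative with CLA in Cy5 and positive with CLA in Cy3.

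In the turned reading, PPAR-alpha target genes were shifted upward as a list (25 measured genes, 22 with a positive value, camera adjusted p = 0.0001), with list means of 0.04, 0.58, 0.31 and 0.34 on arrays 1 to 4. In the planned reading the same list was not shifted, at a mean of -0.0086 ± 0.43 with a median of 0.14 and 15 of 25 values positive (adjusted p = 0.91). The call was not kept with an estimated correlation between genes (adjusted p = 0.67 with an estimated correlation). None of its 25 genes passed the test for single genes, whether adjusted over all genes or adjusted over the list alone. Vnn1, a pantetheinase, was at 0.90 ± 0.19 (SE, n = 4) and Aldh3a2, a fatty aldehyde dehydrogenase, at 0.43 ± 0.12, both with adjusted p = 0.35 in limma. The fatty acid hydroxylase Cyp4a14 had the largest mean of the advance-chosen genes at 1.22 ± 0.48, a 2.33-fold difference, and was above 0 on all 4 arrays, with 3.21 on array 2 and 0.24 to 1.03 on the others. Its relative Cyp4a10 was at 0.54 ± 0.23, the fatty acid transporter Cd36 at 0.74 ± 0.31, the lipid droplet protein Cidec at 0.62 ± 0.34 and the acyltransferase Mogat1 at 0.54 ± 0.23, each with its highest value on array 2. Without array 2 the list mean was 0.18, with adjusted p = 0.0031, and 14 of the 25 genes are also in another list.

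Mitochondrial beta-oxidation and ketogenesis genes gave 20 positive values among 21 measured genes in the turned reading (camera adjusted p = 0.00072; adjusted p = 0.67 with an estimated correlation), with none passing singly. Hadh, a dehydrogenase of the beta-oxidation spiral, was at 0.32 ± 0.08, and the carnitine carrier Slc25a20 at 0.31 ± 0.08, positive on arrays 3 and 4 and just below 0 on arrays 1 and 2. Peroxisomal beta-oxidation and biogenesis gave 17 positive values among 23 genes (adjusted p = 0.0027; 0.67 as the adjusted p with an estimated correlation). There, Decr2, a dienoyl-CoA reductase, was at 0.41 ± 0.09 and above 0 on all 4 arrays, while the transporter Abcd3, at 0.61 ± 0.10, was at -0.82 and -0.93 on arrays 1 and 2 and at 1.89 and 2.30 on arrays 3 and 4. Without array 1 the peroxisomal list lost its call, at adjusted p = 0.078. The planned reading had the mitochondrial list at 0.09 ± 0.18 (adjusted p = 0.46) and the peroxisomal list at -0.10 ± 0.19 with a median of 0.03 (adjusted p = 0.73), neither of them shifted. The list of cytoskeleton and cell shape had 23 positive values among 25 genes, with a mean of 0.18 ± 0.17 and adjusted p = 0.00022 (adjusted p = 0.67 with an estimated correlation). Its list means ran from 0.02 on array 1 to 0.39 on array 4, and in the planned reading it was at -0.14 ± 0.21 (adjusted p = 0.37). Lgals1, a galectin, was at 0.37 ± 0.09 and Anxa2, an annexin, at 0.43 ± 0.12.

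Cholesterol synthesis genes had list means below 0 on arrays 1 and 2, which enter both readings alike, while arrays 3 and 4 pointed the other way in the turned reading. The planned reading had 16 negative values among 20 measured genes and 9 genes past the threshold, all lower with CLA, 12 when adjusted over the list alone. Mvd, the mevalonate decarboxylase, fell by 1.15 (SE 0.08, n = 4, adjusted p = 0.0091 in limma). Mvk and Pmvk, the mevalonate and phosphomevalonate kinases, fell by 0.80 and 0.67, and Lss, the lanosterol synthase, fell by 0.66. The turned values were -0.06 for Mvd, 0.20 for Mvk, -0.17 for Pmvk and -0.26 for Lss. On the turned reading no gene passed over all genes and 5 did when adjusted over the list alone, all lower. The genes with the smallest p were Idi1, an isopentenyl diphosphate isomerase, at -0.51 ± 0.08, and Insig1, a regulator of sterol sensing, at -0.49 ± 0.08, both with adjusted p = 0.35 and below 0 on all 4 arrays. In the planned reading Idi1 was at -0.12 and Insig1 at 0.13, and neither passed, so the 2 readings rest partly on different genes. The list mean of the deposited values was -0.50 and -0.68 on arrays 1 and 2 and 0.21 and 0.14 on arrays 3 and 4. Neither call was kept with an estimated correlation (adjusted p = 0.92 in the planned and 0.67 in the turned reading).

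**Figure D2:**
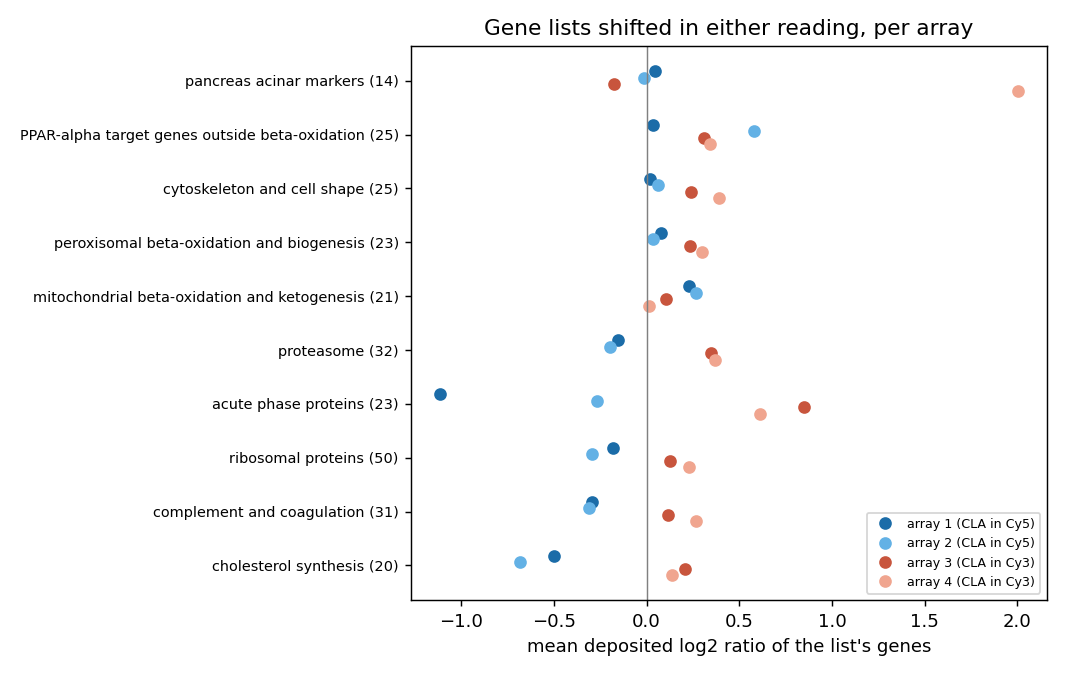
Each row is a gene list that was shifted in at least one reading, with the number of measured genes in parentheses, and the 4 points are the mean deposited log2 ratio of its genes on each array. Blue points are arrays with CLA in Cy5 and red points arrays with CLA in Cy3; acute phase proteins run from -1.11 on array 1 to 0.85 on array 3, while PPAR-alpha targets lie above 0 on all 4 arrays and pancreas acinar markers reach 2.00 on array 4 only.

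The planned reading called 2995 of 17782 probes (16.8%, limma adjusted p under 0.05), 1300 higher and 1695 lower with CLA, and 6881 at an unadjusted p under 0.05. None was higher by over 2 log2 units, and 72 were lower by more than that. The largest decreases were those of Krit1, a protein of endothelial junctions, which fell by 5.78, Gad1, the glutamate decarboxylase of neurons, which fell by 5.74, and 1700102P08Rik, which fell by 5.45. In the turned reading these 3 were at 0.33, 0.37 and 0.13, and none passed. Gpr149, Kat14, Il3, Svop, Ppp2r5e, Gars, Slfn3, Tsga8 and Atrn also fell, with log2 ratios from -4.62 for Gpr149 to -3.69 for Atrn. Over 10-fold from 0 in the part that changes sign with the dyes lay 13 of 18218 named features, against 473 of 4159 unnamed ones. All 473 were negative in that part, which is the direction of the decreases named here. Whether the decreases share a cause with those features was not tested. The largest increases were smaller, with 3830408C21Rik at 1.55, the receptor genes Olfr1057 and Olfr714 at 1.21 and 1.19, and Tmtc2 at 1.14. Their turned values were -0.21, -0.47, -0.79 and -0.74, of the opposite sign, and none passed. Fads2b, Asb17, Sptbn1, Cdc26, Asap2, Dhtkd1, Cmip and B2m, the light chain of class I histocompatibility molecules, rose by 0.97 to 1.08. The count was 600 without array 1, 712 without array 2, and 0 without array 3 or without array 4 (limma, 5103 and 4333 at an unadjusted p under 0.05), with 1 residual degree of freedom in each of these fits. The 24 genes named here kept their size there, with log2 ratios 0.79 to 1.21 times those with all arrays. A dye effect, the coefficient that both orientations share in this reading, passed on 0 probes (limma, 2413 at an unadjusted p under 0.05).

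Acute phase proteins, made by the liver in inflammation, were shifted downward with CLA in the planned reading, with a list mean of -0.71 ± 0.36 (SD, n = 4) over 23 genes and camera adjusted p = 0.010 (adjusted p = 0.92 with an estimated correlation). Of these genes, 7 fell, 1 rose and 15 did not pass. The serum amyloid gene Saa1 fell by 2.56 (SE 0.56, adjusted p = 0.047), a call lost with scaled arrays (adjusted p = 0.085), robust moderation (0.0505), arrays 1 and 3 and arrays 2 and 4 averaged (0.081), without array 3 (0.17) and without array 4 (0.19). Among the others, Saa4 fell by 0.73, the plasma protein gene Itih4 fell by 0.83, and Steap4, a metalloreductase, fell by 1.00. Hamp, which encodes the iron hormone hepcidin, rose by 0.89. In the turned reading the same list had a mean of 0.02 ± 0.89 and adjusted p = 0.99. Complement and coagulation genes had a mean of -0.25 ± 0.09 with 13 lower and 2 higher of 31 genes (adjusted p = 0.020), among them the lectins Mbl2 and Mbl1, which fell by 1.04 and 0.86, the complement gene C4b, which fell by 0.74, and the clotting factor gene F10, which fell by 0.59. The turned value of this list was -0.06 ± 0.29 with 15 of 31 genes positive and none called (adjusted p = 0.39). Ribosomal protein genes were at -0.21 ± 0.07, with 12 of 50 lower and 1 higher (adjusted p = 0.026), and Rps9, Rps14, Rplp0 and Rpl36 fell by 1.08, 0.84, 0.70 and 0.64; turned, the list was at -0.03 ± 0.25 with no gene called (adjusted p = 0.48). Proteasome genes were at -0.27 ± 0.11, with 11 of 32 lower and 1 higher (adjusted p = 0.020), and Psmc5, Psmd13, Psmb5 and Psmd3 fell by 1.16, 0.87, 0.84 and 0.74. With an estimated correlation, each of these lists had adjusted p = 0.92. The proteasome list was shifted the opposite way in the turned reading, at 0.09 ± 0.31 and adjusted p = 0.022 (adjusted p = 0.67 with an estimated correlation), with Psmb10 at 0.44 ± 0.12 and Psmc5 at 0.39 ± 0.12, and that call was lost without array 1 (adjusted p = 0.19), without array 3 (0.063) and in other settings. Without array 4 the complement list had adjusted p = 0.064 and the ribosomal list 0.093, and the latter had 0.058 without array 2.

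Of 35 genes of lipid and glucose metabolism chosen in advance, 28 were measured, and the others were not analysed here. The planned reading called 8 of them. The carnitine palmitoyltransferase Cpt1a rose by 0.45, the peroxisomal enzyme Ehhadh by 0.45 and the glucose-6-phosphatase gene G6pc by 0.71. Thrsp, a lipogenic regulator, fell by 0.83, the desaturase Fads2 fell by 0.82, the lipid binding protein Fabp4 fell by 0.51 and the lipid droplet protein Cidea fell by 1.04, besides Saa1. None of the 8 kept its call without array 3, without array 4 or with arrays 1 and 3 and arrays 2 and 4 averaged. With arrays 1 and 4 and arrays 2 and 3 averaged, 6 of the 8 kept it. Averaging leaves the log2 ratios unchanged by construction, and leaving out array 3 or array 4 gave 0.78 to 1.22 times those with all arrays. Without a dye term 4 of the 8 kept their call. Fads2 (limma adjusted p = 0.0502), Fabp4 (0.083), Ehhadh (0.090) and G6pc (0.11) did not. Only Fads2 and Saa1 kept it without array 1 or without array 2, where Cpt1a had adjusted p of 0.086 and 0.068, Ehhadh 0.084 and 0.10, and G6pc 0.055 and 0.055 in limma. Scd1, at -0.62, and Srebf1, at 0.27, did not pass in the planned reading (limma adjusted p = 0.064 and 0.10). The turned reading called none. There, the lipogenic enzymes Fasn, Acaca, Acly, Me1 and Elovl6 were at -0.14 ± 0.23, 0.13 ± 0.09, 0.15 ± 0.13, 0.35 ± 0.14 and 0.17 ± 0.23, Scd1 at 0.46 ± 0.16 and their regulator Srebf1 at -0.31 ± 0.09, each with an adjusted p between 0.35 and 0.79. G6pc was at -0.54 ± 0.09 and Pck1 at 0.03 ± 0.13. Ppara and Pparg, which encode the receptors, were at 0.10 ± 0.10 and 0.08 ± 0.09, the droplet protein gene Plin2 at 0.33 ± 0.14, the hormone gene Fgf21 at 0.27 ± 0.17, Igfbp1 at -0.22 ± 0.40 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -0.05 ± 0.09.

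**Figure D3:**
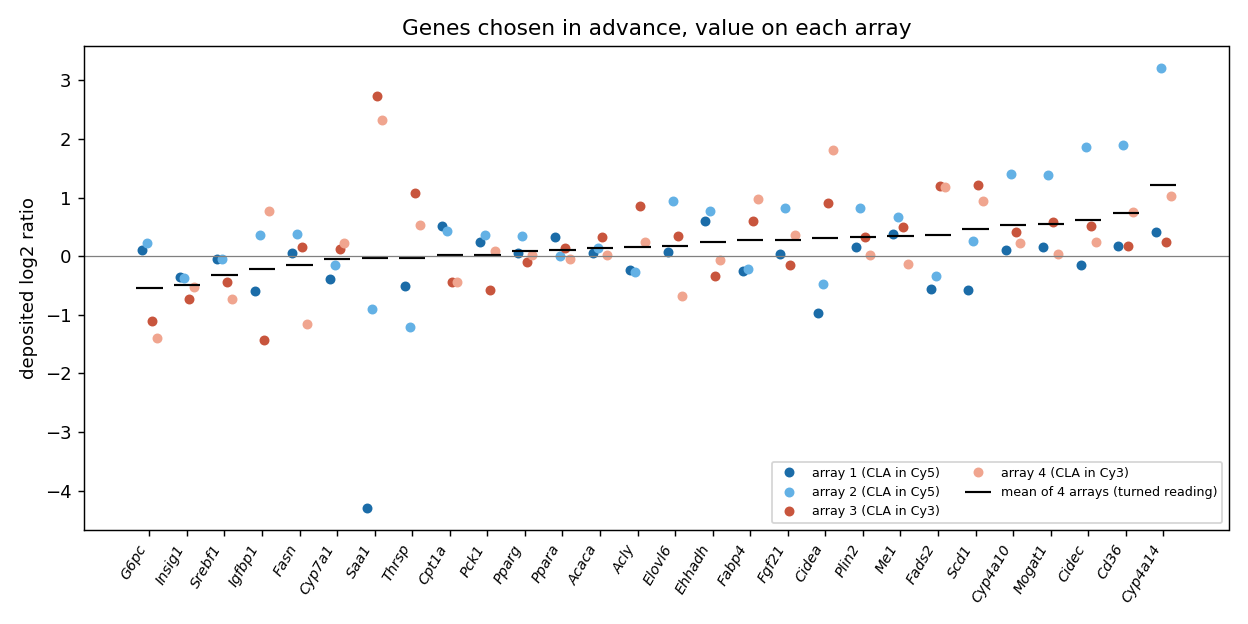
Deposited log2 ratio of 28 genes chosen in advance, with a point for each of the 4 arrays (blue, CLA in Cy5; red, CLA in Cy3) and a line at the mean of the 4, ordered by that mean. Cyp4a14 has the highest mean, 1.22, with 3.21 on array 2, and Saa1 runs from -4.29 on array 1 to 2.73 on array 3.

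No probe passed in the turned reading (limma, lowest adjusted p = 0.35, with 2413 of 17782 at an unadjusted p under 0.05), and 1704 probes (9.58%) had the same sign on all 4 arrays, against 7686 (43.2%) in the planned reading, where chance gives 12.5%. The smallest p values on the higher side belonged to Col4a3, a collagen chain, at 0.68 ± 0.08, the sodium channel gene Scn3a at 0.85 ± 0.10, Slc25a35, Rad51b, H3c1, Rgs16, Cib4, Cdk5rap2, Taf6, Bmp7, Pstk and Fnip1. On the lower side they belonged to Cish, an inhibitor of cytokine signalling, at -1.03 ± 0.09, Olfr1095 at -1.06 ± 0.10, Plekha6, Phlda2, Tspyl4, Art1, Thoc1, Slc26a6, Lenep, Zfp874b, Olfr1179 and Uevld. None of these 24 passed. The mean of the 4 deposited values was related to the feature number, with a Spearman rho of 0.39 across named features.

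Markers of other cell types were set beside these lists. Pancreas acinar markers, genes of digestive enzymes, were called in the turned reading with a mean of 0.46 ± 1.03 over 14 genes and adjusted p = 0.019 (adjusted p = 0.83 with an estimated correlation), and this rests on array 4, where the list mean was 2.00. Without array 4 it was -0.08, without array 3 it was 1.01, and without array 1 the call was lost at adjusted p = 0.092. Ctrb1, a chymotrypsinogen, was at 0.49 ± 0.22 and the elastase gene Cela1 at 0.32 ± 0.16. The beta-oxidation and PPAR-alpha lists kept their direction and their call without array 4, at means of 0.18 for mitochondrial, 0.14 for peroxisomal and 0.31 for PPAR-alpha genes. Hepatocyte markers were at -0.24 ± 0.15 in the planned and 0.13 ± 0.28 in the turned reading, and Kupffer cell markers at -0.11 ± 0.19 and 0.00375 ± 0.23. Adipocyte markers were at -0.21 ± 0.23 and 0.10 ± 0.32, neutrophil markers at -0.03 ± 0.25 (with a median above 0 and the test's direction up) and 0.16 ± 0.17, and skeletal muscle markers at -0.19 ± 0.12 and 0.08 ± 0.23, in the same order. None of the cell type lists except that of the pancreas was called in either reading. Some genes of different lists shared nearly the same deposited values. Alb, Mup5, Serpina1d and Apoa2 were each at 0.53 on array 1, 0.63 on array 2 and -0.14 on array 4, and at 0.54 to 0.91 on array 3. These values enter the means of the hepatocyte, male-biased and lipoprotein lists. Why they are alike was not tested.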

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

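All tests of explanations in this part were chosen after the results were seen, except the count of sign patterns for the planned reading. Among 227 lists and genes, each over 4 arrays, 10 had 1 array far from the other 3 by Dixon's test, and chance flags about 1 in 20, or 11.4. On 6 of the 10 the array was array 4.

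The pancreas acinar list stood apart on array 4 in both readings, with a gap of 0.91 of its range in the planned and 0.90 in the turned reading, and so did Ctrb1 in the turned reading (0.97). On array 4, 12 of 14 measured markers lay over 1 log2 unit from 0, with a list mean of 2.00, and the trypsinogen genes Prss3 and Prss2 were at 3.53 and 3.33 and the lipase relative Pnliprp1 at 3.58. An effect of CLA on these genes is argued against by the mean over arrays 1 to 3, -0.0494 in the turned reading. Pancreas tissue in a pool of array 4 stays open. On that array 22 acinar genes outside the list had a median of 0.47, with 19 of the 22 positive and 4 over 1 log2 unit. This median was above 99.99% of 10000 random lists, of which 95% stay under 0.21. It was below the bound of 0.5 set for this explanation, so the prediction was not met. None of the 14 markers is in another list used here, and how many of them liver also expresses was not tested.

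Unnamed features gave a signal outside the tested probes, with 473 of 4159 over 10-fold from 0, all with negative values on arrays 1 and 2 and positive ones on arrays 3 and 4 in their medians (-8.67, -7.66, 8.75 and 8.54). Against a CLA effect as the whole cause of values that change sign with the dyes, 128 receptor probes were called in the planned reading, where false calls at an adjusted p of 0.05 would give 7.54. Dye bias in values turned to CLA over LA before deposit may account for part of the planned reading, with 14.3% of receptor probes called against 17.0% of others, and as a hypothesis this share and the unnamed features favour the turned reading. Other values differ between receptor and other probes: 96 receptor probes were called higher and 32 lower, against 1300 and 1695 over all probes, and arrays of opposite orientation had a mean r of -0.19 across receptor probes (0.10 for arrays 2 and 3) against -0.44 across named probes. This rests on receptor genes being little expressed in liver, and a CLA effect in part of the other probes stays open. The turned estimate was itself related to the feature number (Spearman rho 0.39 across named features), against -0.07 for the planned one. Which reading this relation favours was not tested.

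The acute phase list differed with the dye orientation, at -0.71 in the planned reading. Dye bias and a CLA effect cannot be told apart, since the list mean has 1 sign on all 4 arrays only in the planned reading and each of the 2 would split the orientations. Arrays 1 and 2, which share an orientation, differed by -0.84, where the next largest difference among 45 lists was 0.54 in size, for PPAR-alpha targets. Dye bias as the whole cause was predicted to leave them no further apart than in other lists, which was not met. This bears on the spread within an orientation and does not decide for a CLA effect. Inflammation that differed between pools was not tested, because the labels do not say which arrays share pools.

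Other values far from the rest of their 4 arrays were these, as a share of the range. Cholangiocyte markers in the planned reading had a gap of 0.87 on array 4 (-0.22 against 0.07 to 0.11). Adipocyte markers in the planned reading had 0.88 on array 2 (0.14 against -0.36 to -0.30). Tsga8 had 0.93 on array 4, Cdk5rap2 in the turned reading 0.84 on array 4, and Acly in the planned reading 0.965 on array 3. Cpt1a had 0.84 on array 1 and Cidec 0.85 on array 2, both in the planned reading.

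Of 8 sign patterns of the 4 arrays, too few for a share under 0.05, the planned reading gave 2995 probes (1 pattern as large) where the highest other gave 0, and 5 lists (5 patterns as large) where the highest other gave 12. The turned reading gave 0 probes (8 patterns as large), the highest other being the planned reading's 2995, and 7 lists (3 patterns as large) where the highest other gave 12.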

How the results depend on the processing

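The tests with the position trend removed, with all features, with unaveraged spots, and all alternatives of the turned reading were chosen after the values were seen, and the others were planned. The estimated correlation was set in advance beside the preset one. Only its use here as an alternative count of shifted lists was chosen afterwards. Robust moderation does not enter the list test, so it could not change a list call. Planned list calls were kept under centring, scaling, no dye term, both ways of averaging arrays and removal of the position trend. In the turned reading the cholesterol synthesis, mitochondrial beta-oxidation, PPAR-alpha and cytoskeleton lists kept direction and call in these settings and without any single array. The proteasome list of that reading lost its call with scaling (adjusted p = 0.13), no dye term (0.16), arrays 1 and 3 and arrays 2 and 4 averaged (0.052), the position trend removed (0.12), and without array 1 (0.19) or array 3 (0.063). The missing-value alternative moved nothing, as no value was missing, and a filter on dim probes was not run, since intensities were not used here; what signal over background limits is therefore unknown. The CLA and LA pools of an array are compared within its ratio, so every fit on the ratios already uses this pairing, and no separate paired analysis was run. Of 24 genes with the largest planned changes, 11 kept their call with arrays 1 and 3 and arrays 2 and 4 averaged, and 0 without array 3 or without array 4 (limma); of 20 named list members 2 and 0 did. With arrays 1 and 4 and arrays 2 and 3 averaged, all 24 and all 20 kept their call. Averaging leaves the log2 ratios unchanged by construction. Without array 3 or 4 the log2 ratios were 0.79 to 1.21 times (the 24) and 0.84 to 1.16 times (the 20) those with all arrays. Those fits had 1 residual degree of freedom, and their loss of calls is not a loss of size. The cause was not tested for any change listed here.

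Probes changed in the planned reading numbered 1152 without a dye term (306 higher, 846 lower), 113 with arrays 1 and 3 and arrays 2 and 4 averaged (0 higher, 113 lower), 5802 at an adjusted p under 0.10 (2860 higher, 2942 lower) and 1274 with a fold of at least 1.5 (329 higher, 945 lower). Scaling left 734 higher. Reading the values as already turned left 0 changed, 0 higher and 0 lower (limma, 2413 at an unadjusted p under 0.05). Without one array the count ran from 0 (array 3 or 4; limma, 5103 and 4333 at an unadjusted p under 0.05) to 712 (array 2), with 600 without array 1, of which 456 were shared with the full set; higher probes ran from 0 to 174 and lower probes from 0 to 538. Shifted lists ran from 3 (without array 4) to 6 (without array 3) in the planned reading and from 4 (without array 1) to 9 (without array 2 or 4) in the turned reading. With an estimated correlation 0 lists were shifted in either reading (camera, 0 at an unadjusted p under 0.05). In simulated data that setting called 0 of 10 lists that were shifted, so a lost call there does not argue against a shift. The fry test also called 0 at an adjusted p under 0.05, its lowest being 0.063 in the planned and 0.19 in the turned reading.

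Read as already turned, these planned results changed sign: the acute phase list to 0.020 and the proteasome list to 0.092; 3830408C21Rik -0.21, Olfr1057 -0.47, Olfr714 -0.79, Tmtc2 -0.74, Fads2b -0.55, Cdc26 -0.55, Asap2 -0.66, Dhtkd1 -0.44, Cmip -0.23 and B2m -0.21; Krit1 0.33, Gad1 0.37, 1700102P08Rik 0.13, Gpr149 1.03, Kat14 0.43, Il3 0.57, Svop 0.63, Ppp2r5e 0.12, Gars 0.66, Slfn3 0.92, Tsga8 0.41 and Atrn 0.35. Among genes fixed in advance these were Fasn -0.14, Acaca 0.13, Acly 0.15, Scd1 0.46, Srebf1 -0.31, Fads2 0.37, Fabp4 0.27, Cidea 0.32, G6pc -0.54, Insig1 -0.49 and Igfbp1 -0.22. Among list members they were Mvk 0.20, Hamp -0.34, Itih4 0.23, Steap4 0.17, Saa4 0.31, Mbl2 0.22, Mbl1 0.16, C4b 0.29, F10 0.083, Rpl36 0.15, Rplp0 0.092, Rps9 0.15, Rps14 0.13, Psmc5 0.39, Psmd13 0.052, Psmd3 0.21 and Psmb5 0.14.

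Leaving out one array changed the sign of these planned values, none of them past the threshold with all 4 arrays and Cyp4a14 past it without array 1 (1.29, adjusted p = 0.049 in limma): Acaca from -0.12 to 0.036, Cyp4a10 from -0.11 to 0.54, Cyp4a14 from -0.11 to 1.29, Ppara from -0.016 to 0.14, Cd36 from -0.15 to 0.72, Plin2 from -0.0062 to 0.33, Cidec from -0.26 to 0.74, Mogat1 from -0.081 to 0.54, Fgf21 from -0.033 to 0.36 and Igfbp1 from -0.44 to 0.66. The low ends of Cyp4a10, Cyp4a14, Cd36, Plin2, Cidec, Mogat1 and Fgf21 are those without array 2. In the turned reading the pancreas list ran from -0.081 (without array 4) to 1.01 (without array 3), Fasn from -0.47 to 0.18, Acly from -0.0050 to 0.31, Thrsp from -0.20 to 0.15, Elovl6 from -0.087 to 0.43, Cpt1a from -0.0062 to 0.037, Cyp7a1 from -0.10 to 0.012, Pck1 from -0.14 to 0.19, Igfbp1 from -0.77 to 0.33 and Saa1 from -0.88 to 0.81. With the position trend removed Cyp7a1 was at 0.046 in the turned reading.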

Other observations

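The list of major urinary proteins and male-biased liver genes had a mean of -0.18 ± 0.07 (SD, n = 4 arrays) over 11 measured genes in the turned reading. The list mean was below 0 on all 4 arrays, 7 of the 11 genes were negative, and camera gave an adjusted p of 0.12. Mup5, the only major urinary protein gene measured, went the other way, at 0.39 ± 0.14 (SE). Its deposited values were nearly those of Alb, Serpina1d and Apoa2, so this value cannot be read as a change of Mup5 alone. Serpina1d, in the same list, was at 0.43. In the planned reading the same list was at -0.03 ± 0.22, with a median of 0.14 and the test's direction up, and Mup5 was at 0.19. Urea cycle and amino acid catabolism genes were at -0.09 ± 0.10 over 33 genes in the turned reading, 23 of them negative, with adjusted p = 0.060, and at -0.06 ± 0.13 in the planned reading (adjusted p = 0.49). Triglyceride synthesis and lipid droplet genes were at 0.16 ± 0.16 in the turned reading with 20 of 28 positive (adjusted p = 0.070), and at -0.13 ± 0.19 in the planned one with 15 of 28 positive and a median of 0.05 (adjusted p = 0.64). Heat shock proteins were at 0.11 ± 0.18 with 13 of 14 positive (adjusted p = 0.10) in the turned reading and at -0.12 ± 0.16 with 5 of 14 positive (adjusted p = 0.37) in the planned one. None of these lists passed in either reading. Female-biased liver genes were at 0.25 ± 0.17 in the planned reading, above 0 on all 4 arrays (adjusted p = 0.23), and at 0.13 ± 0.30 in the turned one, with both signs across arrays (adjusted p = 0.59). Gluconeogenesis and glycogen genes were at 0.18 ± 0.09 in the planned reading, above 0 on all 4 (adjusted p = 0.21), and at -0.07 ± 0.22 in the turned one with 6 of 18 positive (adjusted p = 0.42).

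On arrays 2 to 4 the deposited values rose with the feature number, which stands for the position on the array, with a Spearman rho across named features of 0.31, 0.23 and 0.20, while array 1 had -0.04. The median of the 4-array mean was -0.12 over the first 1822 named features and 0.10 over the last 1822. These relations were looked for only after the values were seen.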
